A study of Macaca fascicularis with 2 samples.

How the data were processed

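Gastrocnemius muscle of the cynomolgus macaque, Macaca fascicularis, was profiled in 2 RNA sequencing libraries. Per the labels, 1 library came from a lean sample on a chow diet and 1 from a non-lean sample on a high fat diet. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was taken on oligo(dT) beads, fragmented and copied from random hexamers, and the amplified libraries were circularised into DNA nanoballs and read on a BGISEQ-500 instrument. No step that marks the RNA strand is named there, and the protocol names both a single-end and a paired-end read format, so the read layout of these libraries, and whether both have the same one, is unclear. Reads of overlapping genes, or of a gene and its antisense partner, cannot be told apart by strand in such libraries.

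The deposited files hold expected counts, which are estimated read counts that need not be whole. Per the file headers each row is a RefSeq transcript with its gene symbol, and each file had 76183 transcript rows. The submitters' processing notes name Trim Galore 0.6.6, STAR 2.7.8a and RSEM 1.3.3 without saying what each was used for. The genome build, the annotation release and any filter are not given in the sources used here. The values were not normalised, since they summed to a different total in each library, and 25702 transcript values in the lean library and 24488 in the non-lean library were not whole. Estimated counts divide reads among transcripts and genes that share sequence, so values of near-identical genes, such as the myosin heavy chains, depend on that division.

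Transcript values were summed per gene and rounded to whole numbers. The files named 28162 genes. Among the symbols, 24 had become dates, as spreadsheet programs do, and these were separated by transcript accession, which gave 28175 genes. Of the 11294 placeholder symbols, 720 took a current name through their NCBI gene number, and 593 older symbols took a current name through their transcripts, from a RefSeq gene table of assembly T2T-MFA8v1.1. That table was used for names and for which genes neighbour, overlap or lie within each other, which may differ in the build behind the files. Members of gene lists were looked up by symbol, and this lookup was extended to the symbols in the files and to 6 older symbols after the files had been examined, because renamed genes had been missed. MYH7, the mitochondrially encoded genes and the sex-linked genes of the lists were not matched by symbol and are not analysed here. The values of 4 members of the gene lists are not reported here, although they count in their lists' medians.

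Libraries were scaled by the trimmed mean of M-values in edgeR 4.0.16 under R 4.3.3, and the scaling factors were 0.952 for the lean and 1.05 for the non-lean library. Scaled CPM values were computed with these library sizes in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Genes with a mean scaled CPM of at least 1 over both libraries are called tested genes, and there were 13707. The log2 ratio of the non-lean over the lean library was taken with a prior count of 0.5 in each library. Its 95% interval is the exact Clopper-Pearson interval of the binomial split of the summed count. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. For a gene with 0 counts in 1 library and more than 3 in the other, the fold was computed against a floor of 3 counts per library, which is 0.197 CPM in the lean and 0.224 CPM in the non-lean library. A gene was counted as higher or lower when it was at least 2-fold apart and its interval excluded 0.

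With 1 library per group the design gives no replicate error. No test between the groups was made, and no p-value is given. The ratio compares these 2 libraries, which may differ in animal, sampling and library preparation as well as in diet and body condition. To place 44 gene lists, the median log2 ratio of the tested members, relative to the median of all tested genes, was set among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and carries no error between animals. Lists with fewer than 5 tested members were given no median. A single gene's percentile was taken among the 500 tested genes nearest to it in mean CPM.

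The groups, the lists, the comparisons, the alternatives and the rule for naming genes were chosen before the data were examined. By that rule every detected gene of the interferon regulatory factor, branched-chain amino acid (BCAA) catabolism and glycogen lists could be named, with IRF4, BCAT1, BCAT2 and PPP1R3C always named. The rule also takes the 12 highest and the 12 lowest genes with a symbol that is not a placeholder, ranked by the bound of the interval nearest to 0, the 2 highest and the 2 lowest tested members of each other list, the 3 most abundant members of each list of another cell type, and the 5 genes with the highest CPM in each library. Any other gene is named with the statement that it was chosen after its values were seen.

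The calculation was tested on simulated data that held counting error only, drawn from the means of the real genes at the real library sizes. Of 13515 unchanged tested genes, 62 were counted as at least 2-fold apart. All 100 of the tested genes simulated at 4-fold and 55 of the 99 at 2-fold were counted in the right direction, and 95.4% of the intervals held the true ratio. Of 200 random unchanged lists, 12 lay outside the central 95%. Alternatives were median-of-ratios size factors from DESeq2 1.42.0, total counts, upper-quartile scaling, total counts without the 50 most abundant genes, no filter on low counts, a mean CPM of at least 5, prior counts of 0 and 5, genes with a symbol only, a 4-fold threshold, and an interval wholly beyond 2-fold.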

Results

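RNA from gastrocnemius muscle, a calf muscle, of cynomolgus macaques was sequenced in 1 lean library from a chow diet and 1 non-lean library from a high fat diet. The comparison asks which genes differ in expression between lean and obese skeletal muscle. The series title names interferon regulatory factor 4 (IRF4) and mitochondrial branched-chain aminotransferase (BCAT2). The lean library held 15983348 counts over 20692 detected genes, and the non-lean library 12731974 counts over 20696 genes. The 10 most abundant genes took 26.8% of the counts in the lean library (95% Clopper-Pearson interval 26.8 to 26.9) and 21.5% in the non-lean library (21.5 to 21.5). Skeletal actin, ACTA1, alone took 7.65% (7.64 to 7.67) and 6.31% (6.30 to 6.33). ACTA1, MYH1, CKM and GAPDH were among the 5 genes with the highest CPM in both libraries, with ATP2A1 in the lean and TNNT3 in the non-lean library. No difference given here has a replicate check, and the intervals in brackets are 95% counting intervals.

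The non-lean library was higher in subunits of the respiratory chain, in slow fibre genes and in genes of fatty acid oxidation. It was lower in genes of lipid and cholesterol synthesis, glycolysis, extracellular matrix and macrophages. Of 13707 tested genes, 673 were at least 2-fold higher in the non-lean library and 982 at least 2-fold lower, so that 40.7% of these genes were higher. With total counts in place of the trimmed mean scaling, the genes at least 2-fold higher in the non-lean library numbered 931 and the genes at least 2-fold lower in the non-lean library 732, a share of 56.0% higher. That scaling moves the median of all tested genes up by 0.14 on the log2 scale. The median log2 ratio of tested genes was -0.01, with quartiles of -0.39 and 0.34. Of the 39 lists with a median, 13 lay below and 6 above the central 95% of their matched random lists, where chance alone gives 1.95, although lists that share members are not independent. The 1.95 also takes the members of a list as independent genes. Genes of a pathway or cell type can move together between single libraries, so the excess over 1.95 is not evidence of a group difference.

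**Figure D1:**
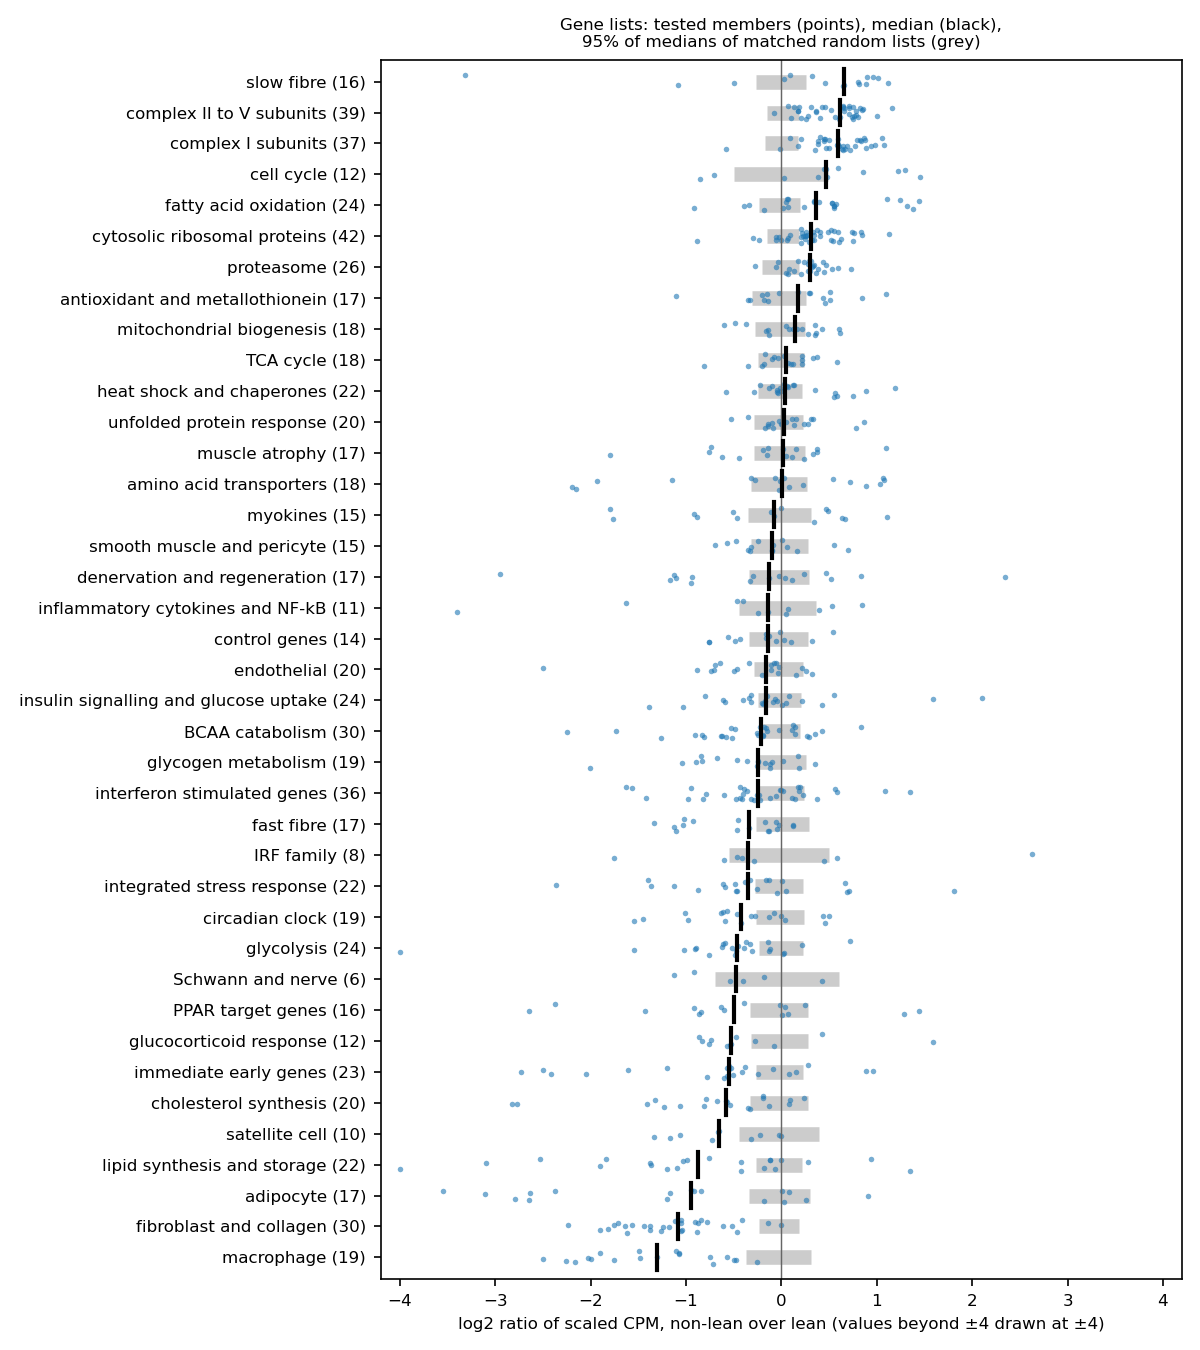
Log2 ratio of scaled CPM, non-lean over lean, on the horizontal axis for the 39 gene lists with at least 5 tested members, with the number of tested members in brackets. Points are genes, black bars are list medians before subtraction of the median of all tested genes (-0.01), and grey bars hold 95% of the medians of 10000 matched random lists; values beyond the axis are drawn at its edge, and the slow fibre list is at the top (0.65) and the macrophage list at the bottom (-1.30).

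IRF4, a transcription factor best known from lymphocytes, had 4 counts in the lean and 24 in the non-lean library. Its scaled CPM was 0.263 in the lean and 1.79 in the non-lean library, a log2 ratio of 2.63 [1.23, 4.76], and it stood at percentile 98.5 of the 500 tested genes nearest in expression. This ratio rests on 28 counts, and the study may have chosen IRF4 on these samples, so the percentile is not independent evidence. The mean CPM of IRF4, 1.03, was just above the cutoff of 1. As 1 count is 0.0657 CPM in the lean and 0.0748 CPM in the non-lean library, genes near that cutoff pass more easily when their counts lie in the non-lean library. Comparisons of IRF4 with tested genes of like expression or summed count share this limit. In the reference gene order the nearest tested gene on one side of IRF4 was EXOC2, an exocyst subunit, with 117 counts in the lean and 2398 in the non-lean library, 23.2-fold higher. The nearest on the other side was DUSP22, chosen after its values were seen, with 435 and 453 counts and a log2 ratio of 0.25 [0.05, 0.44].

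Of the 8 tested IRF family members, the intervals of 2 lay above 0, those of 4 below, and 2 held 0. Beside IRF4, IRF3 was higher at 0.44, while IRF8, a factor of myeloid and lymphoid cells, was lower at -1.76 [-3.05, -0.73] with 36 and 9 counts. IRF1 was lower at -0.60 [-1.06, -0.16] and IRF2 at -0.46. IRF7, an inducer of type I interferon, had 25 and 33 counts and a ratio of 0.58 [-0.21, 1.40] that held 0. The family median was -0.34 relative to tested genes, at percentile 8.94. Macrophage genes stood at -1.29. Of the 4 tested lymphocyte genes, JCHAIN, CD4 and PTPRC were lower, at -2.67, -2.18 and -1.17 [-2.36, -0.17], and GZMB higher, at 1.53.

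BCAT2, the enzyme of the first step of BCAA breakdown in mitochondria, was 1.54-fold lower in the non-lean library. It had 689 counts in the lean and 393 in the non-lean library, a log2 ratio of -0.62 [-0.81, -0.44] at percentile 11.4 of genes with like expression. The cytosolic enzyme BCAT1 had 41 and 19 counts and was lower at -0.90 [-1.79, -0.11]. Of the 30 tested BCAA catabolism genes, 14 had intervals below 0, 6 above, and 10 held 0. IVD and OXCT1, which act in leucine and ketone body breakdown, were lower, with 764 and 381 counts for IVD (-0.82) and 1261 and 621 for OXCT1 (-0.83). PPM1K, the phosphatase that activates the branched-chain keto acid dehydrogenase, was lower at -1.26, and BCKDK, the kinase that inactivates it, at -0.49. The dehydrogenase subunit BCKDHA had a ratio of 0.13 [-0.05, 0.30], and BCKDHB one of -0.51 [-0.90, -0.14]. Among tested members AOX1 and ABAT were the lowest, at -2.25 and -1.73, while MCEE was higher at 0.43. The list median was -0.20 relative to tested genes, at percentile 3.43, inside the central 95% of matched random lists. Of the 6 transcript models of BCAT2, the leading 2 had 292 and 294 estimated counts in the lean and 237 and 156 in the non-lean library, and models with 72.6 and 30.4 in the lean library had 0 in the non-lean library. The study may have chosen BCAT2 on these samples too.

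**Figure D2:**
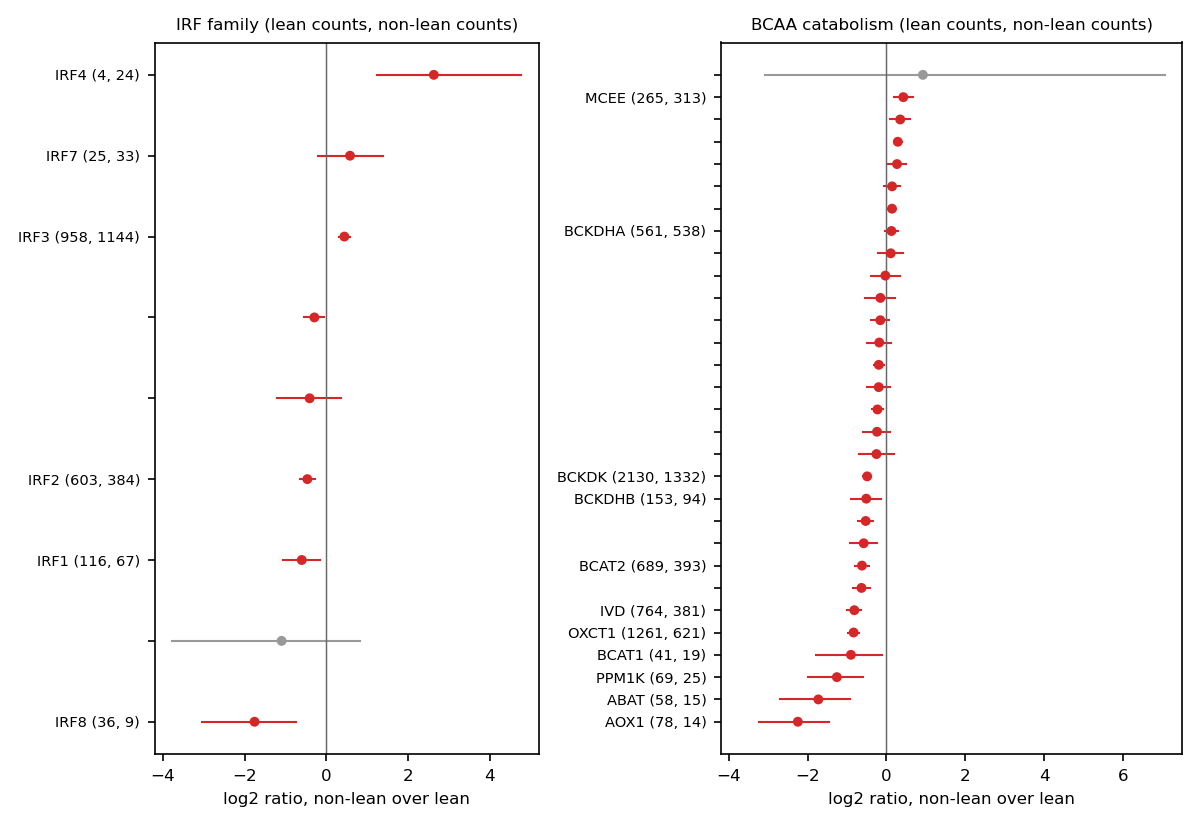
Log2 ratio, non-lean over lean, on the horizontal axis for the genes of the IRF family (left) and of BCAA catabolism (right), with lean and non-lean counts in brackets for the genes named in the text. Points are ratios of all detected members other than the gene not reported here, lines are 95% counting intervals and grey marks genes under the mean CPM of 1; IRF4 lies at 2.63 with a wide interval and BCAT2 at -0.62 with a narrow one.

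Amino acid transporters went both ways, with a list median of 0.02 at percentile 58.0. SLC7A6 and SLC7A5, which carry large neutral or cationic amino acids, were 2.11-fold and 2.09-fold higher, while SLC7A1 and SLC38A1 were lower at -2.19 and -2.15. Genes of the integrated stress response had a median of -0.34 at percentile 0.60, and 14 of 22 had intervals below 0. ATF5 was lowest at -2.37 [-2.60, -2.15], followed by NUPR1 at -1.40, whereas the asparagine synthetase ASNS was higher at 1.81 [0.88, 2.92] and DDIT3 at 0.71.

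Subunits of oxidative phosphorylation were higher in the non-lean library almost throughout. Intervals lay above 0 for 34 of 37 complex I subunits and for 37 of 39 subunits of complexes II to V. The list medians were 0.60 and 0.62 relative to tested genes, both above all 10000 matched random lists. UQCR10 was 2.23-fold higher, NDUFB3 and NDUFB7 were 2.10-fold and 2.08-fold higher, and COX7A1 had 6229 counts in the lean and 10943 in the non-lean library. The intervals of NDUFS1, a large complex I subunit, at -0.58 [-0.72, -0.45], and of ATP5F1A, at -0.08, lay below 0, and ATP5F1A was at 0.063 with total counts. Cytosolic ribosomal proteins, with a median of 0.32 at percentile 99.99, and the proteasome, at 0.31 and percentile 99.94, were also higher, with RPS20 at 1.13 and PSMB4 at 0.73 as their highest members and RPL6 at -0.88 and PSMC6 at -0.28 as their lowest. Beside these groups, 57 genes of other functions known for short transcripts had a median log2 ratio of 0.32 and 60 genes known for long transcripts one of -0.33, sets chosen after the files were examined. The 10 larger oxidative phosphorylation subunits, chosen after the values were seen, had a median of 0.18.

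Genes of the tricarboxylic acid cycle list, whose products work in the same organelle, had a median of 0.06 at percentile 63.9. The list also holds the pyruvate dehydrogenase complex, which feeds the cycle. From that complex came the highest member, PDHA1 at 0.58, and the lowest, PDHX at -0.82. Genes of mitochondrial biogenesis had a median of 0.15 at percentile 88.0, from MFN2 at -0.48 and PRKAA2 at -0.60 to ESRRG at 0.60 and TFB2M at 0.61. Fatty acid oxidation genes were higher, with a median of 0.38 at percentile 99.99 and 15 of 24 intervals above 0. CPT1B, which controls entry of long-chain fatty acids into mitochondria, was 2.73-fold higher with 439 and 1052 counts. The carnitine carrier SLC25A20 was 2.60-fold higher, while LPL, which frees fatty acids from circulating triglyceride, was 1.89-fold lower and the fatty acid transporter CD36 1.31-fold lower.

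Slow fibre genes were higher, with a median of 0.66 above all matched random lists and 11 of 16 intervals above 0. The slow troponin TNNT1 was 2.17-fold and the slow light chain MYL3 2.01-fold higher, but the slow calsequestrin CASQ2 was 9.97-fold lower and ANKRD2 2.12-fold lower. Fast fibre genes were lower, with a median of -0.33 at percentile 0.795 and 15 of 17 intervals below 0. MYH4 and PVALB were lowest at -1.34 and -1.13, and MYL11 and TNNC2 were slightly higher at 0.13 and 0.12. Within the counts of 5 skeletal myosin heavy chains, MYH1 made up 86.2% (86.1 to 86.2) in the lean and 78.6% (78.5 to 78.7) in the non-lean library. MYH7 of the slow fibre list was not matched and is not among the 5, so these shares do not give the fibre type composition. MYH2 made up 12.3% (12.2 to 12.3) and 20.5% (20.4 to 20.6). Its counts were 101799 in the lean and 86266 in the non-lean library, and its interval was among the 15 below 0. In the main scaling the larger share of MYH2 goes with the lower counts of MYH1, 715849 and 330900, and not with a rise of MYH2. MYH2 was not recomputed with total counts, which lift the median of tested genes by 0.14, so the sign of MYH2 may depend on scaling. MYH2 is named here after its values were seen, and these near-identical myosin genes share reads that the estimation divides among them.

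Glycolysis genes were lower, with a median of -0.45 at percentile 0.02 and 20 of 24 intervals below 0. ALDOC was 17.7-fold lower with 472 and 23 counts, and PFKFB3, which makes the activator of phosphofructokinase, was 2.91-fold lower. PGK2 was highest, at 0.72. Glycogen genes had a median of -0.24 at percentile 3.01, and 14 of 19 intervals lay below 0. PPP1R3C, which brings protein phosphatase to glycogen, had 6621 and 3137 counts and was lower at -0.89 [-0.95, -0.83]. Muscle glycogen phosphorylase PYGM was lower at -0.68, glycogen synthase GYS1 at -0.36 and the liver phosphorylase PYGL at -2.01, and UGP2 was higher at 0.35. Insulin signalling genes had a median of -0.15 at percentile 9.30. In that list FOXO1 was 3.01-fold and the receptor-binding adaptor GRB14 4.28-fold higher, while PDPK1 was 2.61-fold and TBC1D4 2.04-fold lower.

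Genes of lipid synthesis were among the furthest below. SCD, the enzyme that makes monounsaturated fatty acids, had 1991 counts in the lean and 29 in the non-lean library, 59.3-fold lower. Fatty acid synthase, FASN, had 1487 and 152 counts, 8.57-fold lower. The lipid synthesis and storage list had a median of -0.86 below all matched random lists, and 16 of 22 intervals lay below 0 and 3 above. The lipid droplet gene PLIN3 at 1.35 and the phosphatidate phosphatase LPIN1 at 0.94 were higher. Cholesterol synthesis genes had a median of -0.57 at percentile 0.04. INSIG1, which holds back sterol synthesis, was lower at -2.77, whereas IDI1 had a ratio of 0.24 [0.07, 0.40], and 12 of 20 intervals lay below 0. Target genes of peroxisome proliferator-activated receptors (PPAR) had a median of -0.49 at percentile 0.23, with CIDEC and CIDEA lowest at -2.65 and -2.38 and CPT1B and PLIN5 highest at 1.45 and 1.29. This percentile was 48.4 among genes with a mean CPM of at least 5. Adipocyte, macrophage and fibroblast markers were lower beside these groups, at medians of -0.94, -1.29 and -1.07, with ADIPOQ at 46 and 3 counts, a log2 ratio of -3.55 [-6.08, -2.11].

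Markers of several interstitial cell types were lower in the non-lean library. The macrophage list had a median of -1.29 below all matched random lists, and 15 of 19 intervals lay below 0 and none above. LYVE1 and VSIG4 were 5.66-fold and 4.79-fold lower, and the complement gene C1QB had 359 and 84 counts. The fibroblast and collagen list had a median of -1.07 below all matched random lists, with 28 of 30 intervals below 0. The fibrillin gene FBN1 was 4.71-fold and COL1A1 3.74-fold lower, whereas FAP had a ratio of -0.01 [-0.39, 0.37] and DPT one of -0.14 [-0.28, 0.01]. The most abundant members, DCN, SPARC and COL6A2, were lower at -0.89, -0.47 and -0.87. Genes known for long transcripts, as those of many matrix proteins are, stood at a median of -0.33. Adipocyte genes had a median of -0.94 below all matched random lists, and this percentile was 32.05 among genes with a mean CPM of at least 5. TRARG1 was 8.63-fold lower, while the abundant members GPD1, PLIN4 and CFD had ratios of 0.03, 0.08 and 0.00, and AQP7 was higher at 0.91. FABP4, which is also in the endothelial list, had 368 and 388 counts and was higher at 0.26 [0.05, 0.47]. Of the 17 intervals of adipocyte genes, 12 lay below 0 and 3 above. Satellite cell genes had a median of -0.65 at percentile 0.27, with DLK1 at -1.33 and NCAM1 at -1.17 lowest, and with MYF5 at -0.02 [-0.99, 0.93] and CHODL at 0.00 [-1.15, 1.12] highest.

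Endothelial genes had a median of -0.15 at percentile 15.0. LYVE1, which is also in the macrophage list, at -2.50 [-2.91, -2.13] and CDH5 at -0.88 were lowest. ENG at 0.32 and FABP4, which is also in the adipocyte list, at 0.26 were highest. The most abundant members, AQP1, VWF and PECAM1, were lower at -0.74, -0.20 and -0.46. Smooth muscle and pericyte genes had a median of -0.09 at percentile 27.1, and 8 of 15 intervals lay below 0 and 2 above. NOTCH3 at -0.70 and CSPG4 at -0.57 [-0.90, -0.26] were lowest. ACTG2 at 0.70, whose interval held 0, and SMTN at 0.55 were highest. The abundant members DES and LMOD1 were at -0.09 and -0.35, and DES alone held 156546 of the 164860 lean counts of the list. Schwann and nerve genes had a median of -0.46 at percentile 8.03, with MBP at -1.12 and PMP22 at -0.92 lowest, PRX at 0.42 [-0.45, 1.32] and NGFR at -0.18 [-1.11, 0.71] highest, and 4 of 6 intervals that held 0. Lymphocyte, neutrophil and erythroid genes were too low for a median, with 4, 0 and 2 tested members. The cytotoxic granule gene GZMB had 8 and 21 counts and was higher at 1.53 [0.35, 2.96], and the haemoglobin gene HBB had 59 and 71 counts.

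Interferon stimulated genes had a median of -0.24 at percentile 2.99, and at percentile 2.11 without the filter on low counts. Intervals lay below 0 for 11 of 36 members and above 0 for 3. MX2 and USP18 were lower at -1.62 and -1.57, and OAS1 and HERC6 higher at 1.35 and 1.09. Inflammatory cytokine and NF-kB genes had a median of -0.13 at percentile 24.6, with the cytokine signalling inhibitor SOCS3 10.6-fold lower (343 and 28 counts) and IL18 1.79-fold higher. Myokines had a median of -0.07 at percentile 33.9, and at percentile 1.07 among genes with a mean CPM of at least 5. Myostatin, MSTN, an inhibitor of muscle growth, was 3.48-fold lower and FSTL1 3.41-fold lower, while APLN was 2.16-fold and FNDC5 1.59-fold higher. Muscle atrophy genes had a median of 0.03 at percentile 55.4, with EIF4EBP1 2.14-fold higher and KLF15 1.69-fold lower.

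Immediate early genes were lower, with a median of -0.54 below all matched random lists and 16 of 23 intervals below 0. FOSB and FOS, which respond to acute stimuli within minutes, were 6.65-fold and 5.66-fold lower, and FOSL1 and NR4A2 were higher at 0.96 and 0.89. Circadian clock genes had a median of -0.41 at percentile 0.17, with ARNTL 2.92-fold and NPAS2 2.73-fold lower and CIART and RORA higher at 0.49 and 0.46. Genes of the glucocorticoid response had a median of -0.52 at percentile 0.03, with ZBTB16 and KLF9 lower at -0.86 and -0.84 and FOXO1 higher at 1.59. The hour of sampling is not stated in the labels.

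The genes furthest apart were a mixed group. S100A1, a calcium sensor of striated muscle, had 353 counts in the lean and 6929 in the non-lean library, 22.3-fold higher. PHYHD1 had 5 and 534 counts, a log2 ratio of 6.79 [5.69, 8.55]. CLEC2L had 0 and 100 counts and was at least 37.9-fold higher against the floor of 3 counts, a bound without the counting error of the 100 counts, while its counting interval reached down to a log2 ratio of 4.92. FAAH2 was 17.1-fold, SEPW1 13.7-fold, SBK2 13.8-fold and IFITM10 11.6-fold higher. GALNT14 had a ratio of 4.75 [3.36, 7.27], ZMAT4 of 4.67 [2.65, 10.58], SYTL3 of 4.31 [3.06, 6.38] and TSTD3 of 4.13 [2.98, 5.92], each on fewer than 90 counts in the non-lean library. On the lower side, ALOX15, a lipoxygenase, had 151 and 4 counts, a ratio of -4.89 [-6.95, -3.67], and CADPS 63 and 1 counts, a ratio of -5.22 [-11.12, -3.26]. MICAL2 was 9.11-fold, TMEM74B 9.84-fold and FNDC1 8.38-fold lower. MYH8, the perinatal myosin heavy chain, had 3282 and 373 counts, 7.72-fold lower. CERS1, a ceramide synthase, had 132 and 0 counts and was at least 38.7-fold lower against the same floor, with a counting interval that reached up to -4.95. It overlaps GDF1 in the reference gene table, and GDF1, chosen after its values were seen, had 803 and 683 counts. The summed counts of the pair were 935 and 683, a log2 ratio of -0.27 [-0.41, -0.12], and the value of CERS1 is uncertain, since reads shared by the pair were not measured here.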

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

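All alternatives were planned, and none was added after the data were examined. The BCAT2 ratio ranged from -0.65 to -0.48 and the IRF4 ratio from 1.87 to 2.77 over the alternatives in scaling, prior count and genes with a symbol, with 1.87 under a prior count of 5, each inside its main counting interval. The BCAA catabolism percentile ranged from 3.08 to 5.92. The number of gene lists outside the central 95% of random lists ranged from 18 to 21. Counts of genes depended on the filter and threshold by construction. The genes at least 2-fold higher in the non-lean library numbered 1082 without the filter on low counts, among them all 673 of the main count. With a mean CPM of at least 5, 231 were higher and 485 lower. At a 4-fold threshold 111 were higher and 176 lower, and with an interval wholly beyond 2-fold 211 were higher and 388 lower. With total counts, which lift the median of tested genes by 0.14, ATP5F1A at 0.063, DES at 0.054 and STBD1 at 0.026, all below 0 in the main scaling by less than that shift. A filter leaves the ratio of a single gene as it is, so single genes were not recomputed under the filters, and IRF4 is not tested at a mean CPM of at least 5. Of 1687 values of named genes under the other alternatives, 1561 stayed within the gene's counting interval, 123 lay outside it, and these 3 had the opposite sign. A change of sign was counted only where the main interval excluded 0. Genes whose main interval held 0 are not among the 3 if they crossed 0. All 348 list medians stayed within their bootstrap interval. These medians are relative to all tested genes, and a change of scaling moves every gene alike. The alternatives in scaling could therefore hardly move the list medians or their percentiles. Adipocyte and PPAR target genes left, and myokines entered, the lists outside the central 95% at a mean CPM of at least 5, where low members such as ADIPOQ are no longer tested. Interferon stimulated genes entered without the filter, and cell cycle genes without the filter (percentile 98.8) and with named genes only (98.5). At a mean CPM of at least 5 the IRF family, cell cycle, and Schwann and nerve lists had fewer than 5 members and gave no value. An alternative with TPM was not run, as the files hold no such values, and the mitochondrially encoded genes, which were not matched, were not part of the removed genes. Depth limits low genes most, as the IRF4 interval spans 1.23 to 4.76. No paired analysis was possible because each group has 1 library.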

Other observations

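The tests of smaller against larger subunits, slow and fast fibre pairs, endothelial genes, adipocyte genes, lymphocyte genes and the neighbour of IRF4 were chosen only after the results they bear on had been seen, so they can speak against an explanation but not for it. Genes of denervation and regeneration had a median of -0.12 at percentile 22.3 but spread widely. The acetylcholine receptor subunit CHRNA1 had 85 counts in the lean and 382 in the non-lean library, 5.09-fold higher, and the fetal subunit CHRNG was higher at 0.84, while the perinatal myosin MYH8 was lower at -2.95 and the adhesion molecule NCAM1 at -1.17. The heat shock and chaperone list had a median of 0.05 at percentile 66.6, with its highest members HSPB3 and HSPB1 at 2.29-fold and 1.84-fold higher and its lowest member HSPB2 at -0.58 [-0.72, -0.44]. Genes of the unfolded protein response had a median of 0.04 at percentile 63.9, from EDEM1 at -0.53 to CRELD2 at 0.86. In the antioxidant list, with a median of 0.18 at percentile 91.1, HMOX1 and SOD2 were higher at 1.09 and 0.85 and the secreted peroxidase GPX3 was lower at -1.10. Cell cycle genes had a median of 0.48 at percentile 97.2, or 98.8 without the filter on low counts, with CCNB2 at 1.45 and TOP2A 2.46-fold higher (9 and 20 counts) but MCM2 at -0.85. Control genes often used for scaling had a median of -0.13 at percentile 19.8, from GUSB and PPIA at -0.76 to RPLP0 at 0.54. The value of PPIA rests on 110 and 57 counts, with an interval of [-1.25, -0.29].

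Among the 37 tested genes at least 16-fold apart, 62.2% had a placeholder name, against 12.8% of all tested genes, and 9 had 0 counts in the lean and 4 in the non-lean library.

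Subunits of oxidative phosphorylation had a median log2 ratio of 0.604 in the non-lean over the lean library. A preference for short transcripts in the non-lean library stays open, as the whole cause or as part of it. The 57 genes of other functions known for short transcripts had a median of 0.325 (95% bootstrap interval 0.236 to 0.462). This is 0.279 (0.111 to 0.403) lower than the median of the subunits. That gap cannot decide the question, because transcript lengths were not measured here and the subunits may have shorter transcripts than the 57 genes. A difference in read format between the libraries, which the labels leave open and which could act by length, stays open too. The 10 larger subunits had a median of 0.176 and the others one 0.471 (0.328 to 0.637) higher. However, NDUFS1 and ATP5F1A among the 10 had been seen to be low. More RNA from slow fibres also stays open: 8 of 9 slow genes lay above the fast gene of the same protein family, by a median of 1.01 (0.118 to 1.29), with CASQ2 the exception, but the pairs come from lists already seen to be apart and add no support. A difference linked to diet or body condition was not tested apart from the animal, as each group has 1 library.

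Fibroblast, macrophage and adipocyte markers and lipid synthesis genes were lower together in the non-lean library. A smaller share of all non-muscle cells, as the whole cause, would lower each type alike, but the fibroblast median lay -0.928 (-1.27 to -0.493) from the endothelial one, which holds LYVE1 of the macrophage list too; as part of the cause it stays open, since the abundant endothelial genes AQP1 (-0.74), PECAM1 (-0.46) and VWF (-0.20) were lower beside DCN (-0.89), COL6A2 (-0.87) and SPARC (-0.47). Fewer fibroblasts could account for the matrix genes, since 32 fibroblast genes other than matrix had a median of -0.871 (-1.10 to -0.526), although lower expression per cell stays open. Fewer adipocytes as a cause of part of the lipid synthesis list stay open. Here 6 adipocyte-specific genes, some already seen to be low, were pooled at 437 and 54 counts, or -2.82 [-3.27, -2.42]. However, CFD, among the most abundant adipocyte genes, stood at 0.00. FABP4, in the adipocyte and the endothelial list, had 368 and 388 counts, or 0.26 [0.05, 0.47]. Of the 21 adipocyte genes found, 7 are in another list and 4 are known in muscle fibres. SCD at -5.89 [-6.50, -5.39] lay further below than those pooled genes. Of the lowest adipocyte genes, TRARG1 at -3.11 [-4.45, -2.14] lay above SCD too, but the interval of ADIPOQ, -3.55 [-6.08, -2.11], overlaps that of SCD. Expression of the pooled genes in other cells would make their ratio less negative and was not measured. A loss of adipocytes as the whole cause for SCD is therefore not excluded, and a difference by diet stays open and untested.

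IRF4 was higher in the non-lean library on 28 counts. More lymphocytes would raise their markers too, but 13 B, plasma and T cell genes had 90 and 42 pooled counts, a log2 ratio of -0.904 [-1.48, -0.37], pooled after B and plasma cells (-1.98) and T cells (-0.14) had been seen apart. The pool cannot speak against a rise of 1 lymphocyte type. The cytotoxic granule gene GZMB had 8 and 21 counts, and its interval of [0.35, 2.96] around 1.53 overlaps that of IRF4. Ordinary spread cannot be told apart from a difference between groups, as 1 library per group confounds them: 3.16% (30 of 948) of tested genes with a like summed count were as far from 0, under a bound of 5% set in advance that would have excluded it, but after the value was seen that bound was judged wrong by design, because the spread over genes holds the group difference too and the gene may have been chosen on these samples. A local difference that IRF4 shares with its neighbour EXOC2, at 4.54 [4.28, 4.82], also stays open, with no test that could support it. Reads from transcription of EXOC2 or a variant of 1 animal would be examples. HUS1B, which lies within the span of EXOC2, was chosen after its values were seen. It had 4 and 4 counts, a log2 ratio of 0.19 [-2.24, 2.61]. That interval overlaps the one of IRF4, [1.23, 4.76], so HUS1B cannot decide the question. Of 534 higher genes placed on the chromosomes, 15.2% had a higher tested neighbour, against 7.82% of the other tested genes.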
